A study of Homo sapiens with 25 samples.

How the data were processed

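Polyadenylated RNA from xenograft tumours was extracted with RNeasy kits and made into libraries with KAPA mRNA HyperPrep kits, per the labels. Per the submitters' processing notes, the authors used fastp, HISAT2 and featureCounts with the hg38 build, with no versions named. The removal of mouse reads, the gene annotation, the use of strand in counting and the tool for normalisation are not given in the sources used here. The 4 deposited tables hold log2 values per gene and library, with 28 columns for 25 libraries because the H1703 vehicle libraries are in 2 tables. Their form was read from the values: each deposited log2 value equalled log2 of the CPM over a library-specific effective size with 0.5 reads added to each gene, and 100% of the values gave whole reads within a tolerance of 0.05 reads. The recovered vehicle reads were identical in both H1703 tables in all 12811 genes they share. The H1703 tables listed 12935 and 12941 genes and had been filtered before deposit, since the third-highest CPM of a gene was never below 0.978 and 0.960. The H2170 and PDX005 tables listed 27777 and 27778 genes. Depth is given as the sum of recovered reads in the listed genes, which for H1703 leaves out the genes removed before deposit. A fold change of log2(CPM) with 0.5 reads added understates the change of genes with few reads.

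Libraries were grouped by model and treatment, as the labels give them. The labels call the libraries of a group biological replicates, and whether each came from its own animal is not stated. P-values therefore measure the spread between these libraries, and libraries that shared an animal would not be independent. For H2170, 2 vehicle columns carry the same header, and these libraries are called unnumbered-a and unnumbered-b. Every pair of replicates differed by more than sampling noise, with chi-square per degree of freedom from 14.0 to 247 over genes with 20 or more reads, so each library was counted once.

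Each of 6 comparisons was fitted with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3 on the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 4 comparisons with vehicle used the libraries of their own table. For TAK228+EIPA against TAK228 the 9 H1703 libraries were put on 1 scale by median-of-ratios factors from the recovered reads. The difference between the TAK228 responses of H2170 and H1703 was an interaction term over 12 libraries, and levels were never compared between tables. Genes entered with 10 or more reads in at least as many libraries as the smaller group holds. Gene lists with 5 or more tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The lists (42), the comparisons, the test and the rule for naming genes were fixed before the data were examined. The design had assumed values to be logged after adding 1, but the tables already held log2 values, so these were used as deposited.

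Genes were named by this rule: in each comparison with vehicle the 6 genes with the largest rise and the 6 with the largest fall among those that passed, with a mean of 100 or more reads and no overlap between groups, up to 4 members with the smallest adjusted p of each list described, and 16 genes fixed by name, of which 14 are reported. In the 2 other comparisons the 5 largest differences in each direction were taken, and where fewer genes passed, those with the smallest p. The genes fixed by name are not all given in every comparison, also where they were tested. Of the genes fixed by name, SOX2 and PECAM1 (both H1703 tables) and TXNIP (the TAK228+EIPA table) were not listed, and PECAM1 was under the filter in H2170 and PDX005. Genes outside the rule are marked as chosen after their values were seen. Symbols were matched to GENCODE v29 for hg38 coordinates, and mitochondrial genes and older symbols to RefSeq symbols after the tables were read. Transcript length and GC content were known for 97.8% to 98.8% of the genes tested in a comparison, and for no mitochondrial gene.

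The alternatives planned were pseudocounts of 5 and 0.1, no filter and a stricter filter at a mean of 100, quantile normalisation, array weights, the replicate number as a block, leaving out each library in turn, and the fry rotation test for lists (statmod 1.5.0). Added after the data were seen were a correction that subtracts from each library a spline in transcript length and GC content (5 degrees of freedom each), voom weights from the recovered reads, and the block for H2170 with its unnumbered libraries taken as replicates 1 and 2 in either order. Planned tests with count models were not run, since the deposited unit is log2 values, although whole reads could be recovered from them. The steps were tested on simulated data drawn from the real genes' means, with their spreads shuffled between genes and 200 genes changed. Of the genes changed 2-fold and 4-fold the test recovered 22% and 79% for H1703 TAK228 (12935 genes), 29% and 77% for H1703 TAK228+EIPA (12941 genes), 51.5% and 86% for H2170 (14734 genes), 72% and 95% for PDX005 (15239 genes), 27% and 89% for TAK228+EIPA against TAK228 (12811 genes), and 25% and 79.6% for the difference between models (11796 genes). False calls made up 2.88%, 9.40%, 6.21%, 7.22%, 5.69% and 5.50% of all calls in the same order. The simulated genes varied independently and held no length trend, unlike the real data, in which the trend was strongest in the H1703 comparisons with vehicle.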

Results

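RNA sequencing of polyadenylated RNA was available for 25 tumour libraries from 3 models of human lung squamous cell carcinoma grown as xenografts in mice. H1703 and H2170 are established human lung cancer cell lines, and PDX005 is a tumour line passaged as patient-derived xenografts. TAK228 (sapanisertib) inhibits the kinase mTOR in both of its complexes and was given at 1 mg per kg. EIPA, an amiloride derivative, is widely used to block macropinocytosis, the uptake of extracellular fluid in large vesicles. It was given at 0.75 mg per kg. CB839 (telaglenastat) blocks the use of glutamine by cells and was given at 200 mg per kg. The H1703 tumours formed vehicle, TAK228 and TAK228+EIPA groups of 3 libraries each. The H2170 tumours formed vehicle and TAK228 groups of 3, and the PDX005 tumours vehicle and TAK228+CB839 groups of 5. Reads in the listed genes came to between 24.1 and 27.9 M per library in the H1703 table of vehicle and TAK228, between 22.7 and 26.9 M in the H1703 table of vehicle and TAK228+EIPA, between 39.8 and 47.9 M for H2170, and between 38.2 and 48.2 M for PDX005. The median standard error of a gene's log2 fold change was 0.24 in both H1703 comparisons with vehicle, 0.15 in H2170 and 0.13 in PDX005. Changes are log2 fold changes against vehicle ± SE from limma, and a gene is said to have risen or fallen only where its Benjamini-Hochberg adjusted p was under 0.05.

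The first comparison asked how H1703 tumours responded to TAK228 alone. IRS2, the insulin receptor adaptor that FOXO factors transcribe, averaged 3.41 ± 0.856 CPM in vehicle tumours and 8.74 ± 1.08 CPM under TAK228 (SD, n = 3), a log2 difference of 1.38 ± 0.27 (adjusted p = 0.0635). The proliferation marker MKI67 stood at -0.96 ± 0.23, the squamous transcription factor TP63 at -1.21 ± 0.36, the angiogenic growth factor VEGFA at -0.84 ± 0.21, the leucine transporter SLC7A5 at -0.76 ± 0.21 and the mevalonate pathway enzyme HMGCS1 at -0.85 ± 0.27. None of these passed the test (adjusted p between 0.0635 and 0.0655), nor did DDIT4, a stress-induced inhibitor of mTOR complex 1, at -0.28 ± 0.22 (adjusted p = 0.357). No gene of 12935 passed in limma, where 5201 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0635. With voom weights 0 genes passed as well, with 5130 at an unadjusted p under 0.05. In 5289 genes (40.9%) the TAK228 and vehicle libraries did not overlap, against 10% by chance. Without TAK228 replicate 1 the count of genes passing was 6395, with 7249 at an unadjusted p under 0.05. Without any other library 0 genes passed. Those at an unadjusted p under 0.05 were then 4219, 4504 and 2649 without vehicle replicates 1, 2 and 3. They were 3146 and 2927 without TAK228 replicates 2 and 3, and 3399 after the length and GC correction.

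As no gene of the first comparison passed, the genes with the smallest p are given as values. Above vehicle these were the stress-induced transcription factor DDIT3 (CHOP) at 1.45 ± 0.26, the Notch target HES1 at 1.16 ± 0.22, SLC22A17 at 1.11 ± 0.21, FXYD6 at 1.37 ± 0.26, TMEM54 at 1.39 ± 0.25, and the small nucleolar RNA host gene SNHG5 at 1.82 ± 0.33. Below vehicle were FZD5, a Wnt receptor, at -1.65 ± 0.30, the transcription factor GATA2 at -1.19 ± 0.23, the AKT phosphatase PHLPP2 at -1.36 ± 0.25, LRRC8B at -1.67 ± 0.30, ZNF107 at -1.36 ± 0.24 and the matrix link protein HAPLN1 at -1.05 ± 0.20. As a list, genes for ribosomal proteins and translation factors were higher than other genes. Of 84 members tested 0 passed over all genes and 79 when adjusted over the list alone, with a median log2 fold change of 1.04, or 0.58 after correction for length and GC content (camera adjusted p = 7.24e-19, and adjusted p = 0.984 with an estimated correlation). RPS28 stood at 1.54 ± 0.37 and RPL34 at 1.20 ± 0.30. The nuclear-encoded respiratory chain was also higher as a list, with a median of 0.71 (0.26 after correction for length and GC content) over 44 members, of which 31 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.23e-08, and adjusted p = 0.984 with an estimated correlation). NDUFS7 stood at 1.20 ± 0.31 and NDUFS8 at 1.33 ± 0.36. The macropinocytosis machinery was not called (0 of 31 members passed over all genes, and 3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.185), with the early endosome GTPase RAB5A at -1.25 ± 0.30. In this comparison fold changes followed transcript length: the median was 0.63 in the 20% of genes with the shortest transcripts and -0.48 in the 20% with the longest.

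**Figure D1:**
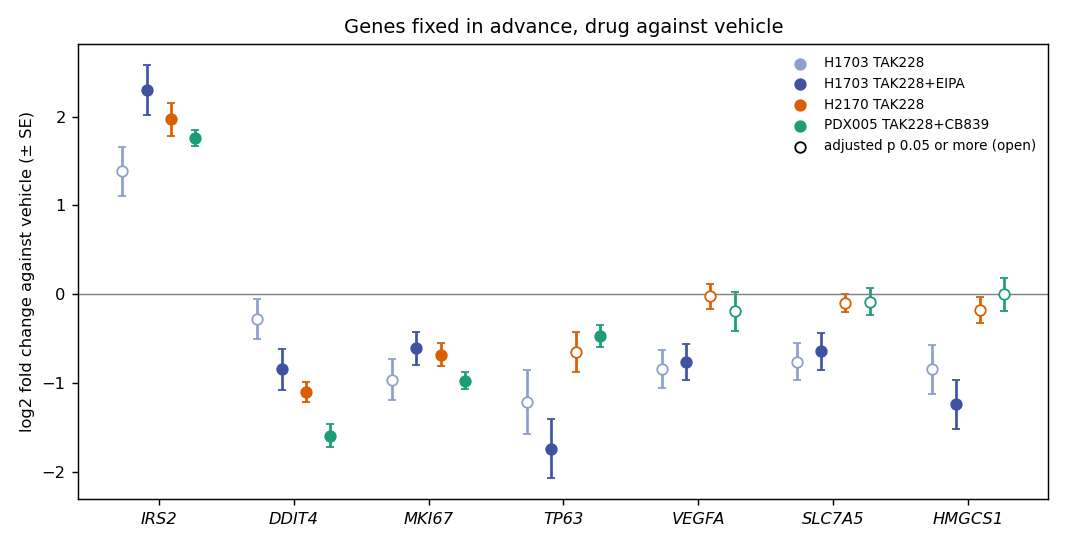
Log2 fold change against vehicle (y axis, ± SE) of 7 genes fixed in advance, with points coloured by comparison and open where the adjusted p was 0.05 or more. IRS2 lay between 1.38 and 2.30 in the 4 comparisons, and DDIT4 stood at -0.28, -0.85, -1.10 and -1.59.

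TAK228 combined with EIPA was compared with vehicle in H1703 to ask what mTOR inhibition changed when macropinocytosis was blocked as well. IRS2 (hg38 chromosome 13, 109752698 to 109786568) rose by 2.30 ± 0.28, from 3.36 ± 0.849 to 16.5 ± 3.82 CPM (SD, n = 3), and HIF1A, the oxygen-labile subunit of the hypoxia-inducible factor (hg38 chromosome 14, 61695513 to 61748259), fell by 2.78 ± 0.31, from 84.6 ± 21.1 to 13 ± 6.5 CPM. HAPLN1, which ties hyaluronan to proteoglycans in the matrix (hg38 chromosome 5, 83637805 to 83721613), fell by 3.29 ± 0.40. TP63 fell by 1.74 ± 0.33 and HMGCS1 by 1.24 ± 0.28. In limma 5841 of 12941 genes passed, 2836 higher and 3005 lower, of which 2927 changed more than 2-fold. The other leading rises were the small nuclear RNA RN7SK, which binds the elongation factor P-TEFb (2.62 ± 0.38), the mitochondrial histidine tRNA gene TRNH (2.56 ± 0.44), SNHG5 (2.29 ± 0.26), AGPAT4-IT1 (2.38 ± 0.54) and the pseudogene RPL21P44 (2.44 ± 0.62). The other leading falls were ANKRD36BP1 (-3.75 ± 0.38), CRYBG3 (-3.11 ± 0.35), the phospholipid flippase subunit TMEM30A (-2.92 ± 0.37) and the fatty acid elongation enzyme HACD2 (-2.78 ± 0.34). RPL21P44, ANKRD36BP1 and AGPAT4-IT1 are uncertain, since the first 2 share sequence with related genes and the last lies within another gene. RN7SK and TRNH are uncertain too, since libraries of polyadenylated RNA are not made to capture small nuclear RNAs or tRNAs.

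Genes of translation and respiration were higher as lists under TAK228+EIPA. Of 84 ribosomal protein and translation factor genes 74 rose and 0 fell (76 higher adjusted over the list alone), with a median of 1.24, or 0.72 after correction for length and GC content (camera adjusted p = 1.79e-18, and adjusted p = 0.975 with an estimated correlation). RPS28 rose by 2.05 ± 0.27 and RPS21 by 1.78 ± 0.25. Of 44 nuclear-encoded respiratory chain genes 31 rose and 1 fell, the same counts as adjusted over the list alone, with a median of 0.79, or 0.29 after that correction (camera adjusted p = 8.61e-08, and adjusted p = 0.975 with an estimated correlation), among them NDUFA2 (1.38 ± 0.22) and NDUFS3 (1.26 ± 0.21). The macropinocytosis list was not called (camera adjusted p = 0.236), with 6 members higher and 11 lower of 31 (6 and 12 adjusted over the list alone). RAB5A fell by 2.14 ± 0.28, the Rac activator DOCK1 by 1.43 ± 0.28 and the actin-nucleating subunit ACTR2 by 1.32 ± 0.24, while RAB34, a GTPase of macropinosome formation, rose by 1.30 ± 0.23. The cell surface proteoglycan SDC1 rose by 0.60 ± 0.19 with all 6 libraries, but its adjusted p was 0.0825 without vehicle replicate 1, 0.111 without vehicle replicate 3, 0.0838 without TAK228+EIPA replicate 1 and 0.406 after correction for length and GC.

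Further metabolic and signalling genes fell under TAK228+EIPA without their lists being called, with the same counts in these lists when adjusted over the list alone. The hypoxia list held 9 falls and 0 rises among 20 members (camera adjusted p = 0.236), including the oxidoreductase ERO1A (-1.14 ± 0.19). Glutamine metabolism held 10 falls and 0 rises among 21 (camera adjusted p = 0.138), including the purine synthesis enzyme PPAT (-1.49 ± 0.24), and fatty acid synthesis 7 falls and 0 rises among 12 (camera adjusted p = 0.0706), including ACLY (-1.09 ± 0.26). The amino acid transporters SLC38A1 (-1.41 ± 0.23) and SLC7A1 (-1.36 ± 0.22), the adaptor IRS1 (-1.51 ± 0.25), the cytokinesis gene ANLN (-1.81 ± 0.32) and the interferon-induced OAS3 (-2.63 ± 0.32) fell as well. VEGFA fell by 0.76 ± 0.20, with an adjusted p of 0.0508 without vehicle replicate 3 and 0.0501 without TAK228+EIPA replicate 1. DDIT4 fell by 0.85 ± 0.23 (0.0683 without vehicle replicate 1). SLC7A5 fell by 0.64 ± 0.21, with adjusted p of 0.119, 0.0539 and 0.115 without vehicle replicate 1, vehicle replicate 2 and TAK228+EIPA replicate 1. MKI67 fell by 0.61 ± 0.19, with 0.0660, 0.0920 and 0.0714 without vehicle replicate 2, vehicle replicate 3 and TAK228+EIPA replicate 1, and 0.438 after the length and GC correction.

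Lists fixed in advance for other cell types and for RNA quality held changes in both directions in the same tumours. The fibroblast list held 3 rises and 4 falls among 13 members, its median (0.34) and mean (-0.15) differed in sign, and camera's direction was down (adjusted p = 0.864). PDGFRA, known to be amplified in H1703 cells, fell by 1.48 ± 0.29, and THY1 rose by 1.12 ± 0.24. The endothelial gene EGFL7 rose by 1.48 ± 0.29 (0.53, adjusted p = 0.103, after the length and GC correction). GAS5 rose by 1.72 ± 0.26 and SNHG1 by 0.95 ± 0.22, while the mitochondrially encoded ATP8 fell by 1.42 ± 0.29. GAS5 and SNHG1 are small nucleolar RNA host genes, so their rise is not read as a change of RNA quality. Fold changes again followed transcript length, with a median of 0.71 in the 20% of genes with the shortest transcripts and -0.56 in the 20% with the longest, and 3344 genes passed after length and GC content were corrected for. The count was 2843 without vehicle replicate 3 and 3806 without TAK228+EIPA replicate 1.

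**Figure D2:**
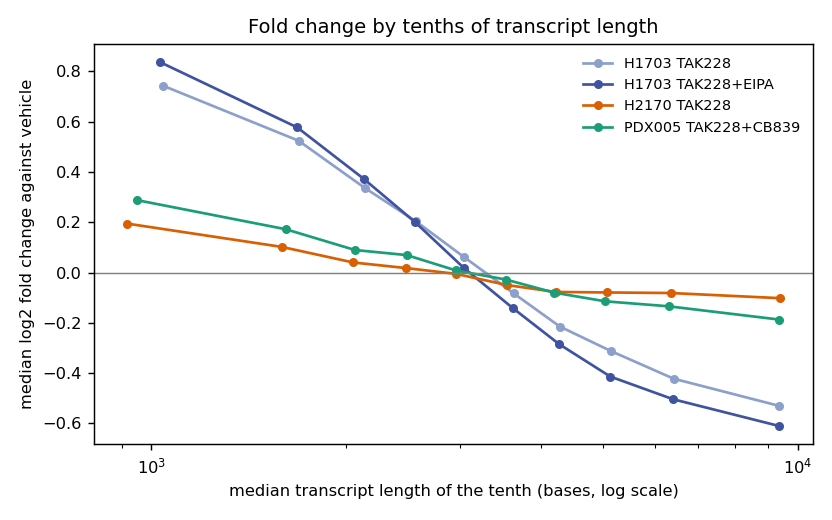
Median log2 fold change against vehicle (y axis) of genes in 10 groups of equal size by transcript length (x axis, bases, log scale), with 1 line per comparison. The line of H1703 TAK228+EIPA ran from 0.84 in the shortest group to -0.61 in the longest, and the lines of H2170 and PDX005 were flatter.

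The effect of adding EIPA was tested directly by comparing TAK228+EIPA with TAK228 in all 9 H1703 libraries. LINC02167, a long noncoding RNA chosen after its values were seen, fell by 2.30 ± 0.21 (adjusted p = 0.00300), from 14.9 ± 2.11 CPM under TAK228 to 3.04 ± 0.459 CPM (SD, n = 3), with 16.5 ± 1.20 CPM in vehicle. It was the 1 gene of 12811 that passed in limma, and its adjusted p was 0.0511 without TAK228 replicate 3. With only the 6 drug-treated libraries 0 genes passed (276 at an unadjusted p under 0.05). At an unadjusted p under 0.05 there were 430 genes, fewer than the 641 that chance would give. That count lay on either side of chance under alternatives. It was 1145 without TAK228 replicate 2, 1016 without TAK228+EIPA replicate 2, 999 with array weights, and 172 without TAK228+EIPA replicate 1. Among the genes with the smallest p, the matrix genes HAPLN1 (-2.20 ± 0.39) and EDIL3 (-1.54 ± 0.34), the anti-angiogenic factor SERPINF1 (-1.11 ± 0.26), the adhesion adaptor BCAR1 (-0.81 ± 0.19) and MEOX1 (-1.22 ± 0.32) had lower values with EIPA, and SOWAHC (0.89 ± 0.21), DNASE1 (0.97 ± 0.25), PXDN (0.71 ± 0.18), MAP1B (0.70 ± 0.18) and ZDHHC14 (0.59 ± 0.16) higher ones, with adjusted p of 0.813 for HAPLN1 and 0.956 for the rest. Of the macropinocytosis list 0 of 31 members passed, also when adjusted over the list alone (camera adjusted p = 0.802). Cholesterol synthesis and interferon-stimulated genes were lower as lists and G1/S genes higher, each at a camera adjusted p of 0.0478, and at an adjusted p of 0.962 with an estimated correlation, while 0 members passed on their own. The cholesterol call was lost without TAK228 replicate 2, TAK228 replicate 3 or TAK228+EIPA replicate 3 (adjusted p = 0.0603, 0.143 and 0.715), and the interferon call without TAK228 replicate 2 or TAK228+EIPA replicate 2 (0.0603 and 0.255) and after the length and GC correction (0.0517). The G1/S call was lost without TAK228+EIPA replicate 2 (0.701) and turned down without TAK228 replicate 2 (0.782).

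H2170 tumours were compared under TAK228 and vehicle to follow the same drug in another model. EGR1, an immediate-early transcription factor (hg38 chromosome 5, 138465490 to 138469315), rose by 2.85 ± 0.18, from 19.2 ± 4.24 to 137 ± 28 CPM (SD, n = 3). IRS2 rose by 1.97 ± 0.18 and TXNIP, an arrestin that restrains glucose uptake, by 1.43 ± 0.14. TRIM29, a gene of basal and squamous epithelia (hg38 chromosome 11, 120111275 to 120185529), fell by 3.07 ± 0.25, from 31.4 ± 8.03 to 3.76 ± 1.05 CPM. DDIT4 fell by 1.10 ± 0.11 and MKI67 by 0.68 ± 0.13. In limma 2005 of 14845 genes passed, 925 higher and 1080 lower, of which 481 changed more than 2-fold. The count was 735 without vehicle replicate 3, 741 and 1047 without vehicle unnumbered-b and unnumbered-a, and 1250 without TAK228 replicate 3. The other leading rises were AMY2B (2.17 ± 0.28), FAR2P1 (2.02 ± 0.30), CCDC18-AS1 (2.00 ± 0.19) and CCDC17 (1.94 ± 0.31), of which the first 2 share sequence with near copies and the third overlaps a gene on the other strand, so their values are uncertain. The other leading falls were the activin subunit gene INHBB (-2.19 ± 0.33), CRYBG2 (-2.13 ± 0.17), the peptide hormone gene ADM2 (-2.10 ± 0.37), the collagen gene COL5A1 (-2.09 ± 0.22) and the nucleotide receptor P2RY2 (-1.92 ± 0.16).

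Camera called 20 of 37 lists in H2170, and growth, lineage and metabolic lists were among those lower under TAK228. Of 23 squamous lineage genes 6 fell (9 adjusted over the list alone, camera adjusted p = 2.27e-05, and adjusted p = 0.615 with an estimated correlation), including KRT6A (-1.89 ± 0.23, a gene with near copies), CLCA2 (-1.23 ± 0.19) and the adhesion gene NECTIN1 (-0.85 ± 0.11). TP63 stood at -0.65 ± 0.22 (adjusted p = 0.0805, from 0.0452 with the length and GC correction to 0.242 under alternatives other than the replicate block) and SOX2 at 0.10 ± 0.15 (adjusted p = 0.676). Of 32 G1/S and replication genes 10 fell (10 over the list alone, camera adjusted p = 0.00015, and adjusted p = 0.615 with an estimated correlation), including CCND1 (-0.70 ± 0.10), CDC25A (-0.88 ± 0.14) and RRM2 (-0.81 ± 0.15), and of 30 G2/M genes 9 fell (12 over the list alone, camera adjusted p = 0.00108, and adjusted p = 0.615 with an estimated correlation), including PLK1 (-0.76 ± 0.14). Of 21 glycolysis genes 7 fell, such as HK1 (-0.62 ± 0.09), and HK2 stood at -0.28 ± 0.18 (list, with the same count over the list alone: camera adjusted p = 0.000679, and adjusted p = 0.615 with an estimated correlation). Of 13 fatty acid synthesis genes 2 fell (3 over the list alone), FASN by 0.54 ± 0.10 and FADS2 by 0.99 ± 0.15 (camera adjusted p = 0.00205, and adjusted p = 0.615 with an estimated correlation). Of 21 TCA cycle genes 6 fell (9 over the list alone, camera adjusted p = 0.00313, and adjusted p = 0.615 with an estimated correlation). Of 25 cholesterol genes 4 fell, while HMGCS1 stood at -0.18 ± 0.15 (8 lower and 1 higher over the list alone, camera adjusted p = 0.00313, and adjusted p = 0.615 with an estimated correlation). That call was lost without vehicle unnumbered-b (adjusted p = 0.0809). Of 32 ATF4 targets 6 fell (8 over the list alone, camera adjusted p = 0.00385, and adjusted p = 0.615 with an estimated correlation), including the pseudokinase TRIB3 (-0.72 ± 0.14), while ASNS stood at 0.03 ± 0.11 and SLC7A5 at -0.10 ± 0.10.

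Of 31 macropinocytosis genes 4 fell and 0 rose in H2170, the same counts as adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.615 with an estimated correlation), and the list's call was lost without TAK228 replicate 1 (0.0952), with quantile normalisation (0.165) and after the length and GC correction (0.122). SDC1 fell by 0.86 ± 0.12 and the recycling endosome ATPase EHD1 by 0.90 ± 0.13. VEGFA stood at -0.02 ± 0.14 (adjusted p = 0.929). Of 36 lysosome genes 6 fell and 1 rose (camera adjusted p = 0.0346, and adjusted p = 0.615 with an estimated correlation), including the proton pump subunit ATP6V0A1 (-0.75 ± 0.11), and the list's call was lost without vehicle replicate 3, TAK228 replicate 1 or TAK228 replicate 3 (0.0662, 0.141 and 0.0663) and with quantile normalisation (0.151). Of 16 fibroblast genes 7 fell (8 over the list alone, camera adjusted p = 0.000515, and adjusted p = 0.615 with an estimated correlation), including the collagen genes COL1A1 (-1.04 ± 0.12), COL1A2 (-0.99 ± 0.13) and COL3A1 (-1.02 ± 0.13), and the smooth muscle actin gene ACTA2 fell by 0.73 ± 0.13. The endothelial gene VWF fell by 1.55 ± 0.37, with adjusted p of 0.0894, 0.0832 and 0.0670 without vehicle unnumbered-b, vehicle replicate 3 and TAK228 replicate 2. The tumour epithelium list was called lower too, with 1 fall among 10 members (2 over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.615 with an estimated correlation). That call was lost without vehicle unnumbered-a, vehicle unnumbered-b or TAK228 replicate 3 (0.0820, 0.0818 and 0.113). Whether reads of the host mouse were removed before counting is not given in the sources used here.

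Lists for FOXO targets, translation and RNA classes were higher in H2170 under TAK228. Of 21 FOXO target and receptor feedback genes 5 rose (camera adjusted p = 0.00313, and adjusted p = 0.615 with an estimated correlation), including KLHL24 (1.35 ± 0.14), and 6 rose and 1 fell adjusted over the list alone. Of 83 ribosomal protein and translation factor genes 9 rose, such as RPL14 (0.69 ± 0.13), but 1 did adjusted over the list alone, and the median was 0.31, or 0.17 after the length and GC correction (camera adjusted p = 1.62e-07, and adjusted p = 0.615 with an estimated correlation). Of 7 genes on the list named nuclear-retained RNAs 5 rose (7 over the list alone, camera adjusted p = 5.58e-06, and adjusted p = 0.615 with an estimated correlation). NEAT1 rose by 1.81 ± 0.15, NKTR by 1.27 ± 0.13, GAS5 by 0.80 ± 0.13 and SNHG1 by 0.72 ± 0.14. As GAS5 and SNHG1 are small nucleolar RNA host genes, the list does not measure nuclear retention alone. Of 13 mitochondrially encoded genes 4 rose (8 over the list alone, camera adjusted p = 6.72e-05, and adjusted p = 0.615 with an estimated correlation). Of 16 replication-dependent histone genes, whose mRNAs lack poly(A) tails, 3 rose, including H2BC5 (1.19 ± 0.21) (camera adjusted p = 0.0116, and adjusted p = 0.615 with an estimated correlation), and that list was no longer called without TAK228 replicate 2 (0.113) or after the length and GC correction (0.104). Of 14 immediate-early genes 4 rose and 1 fell, with KLF2 at 1.27 ± 0.21 (camera adjusted p = 0.0346, and adjusted p = 0.615 with an estimated correlation), and the call was lost without vehicle unnumbered-b, vehicle replicate 3 or TAK228 replicate 2 (0.0759, 0.110 and 0.161).

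**Figure D3:**
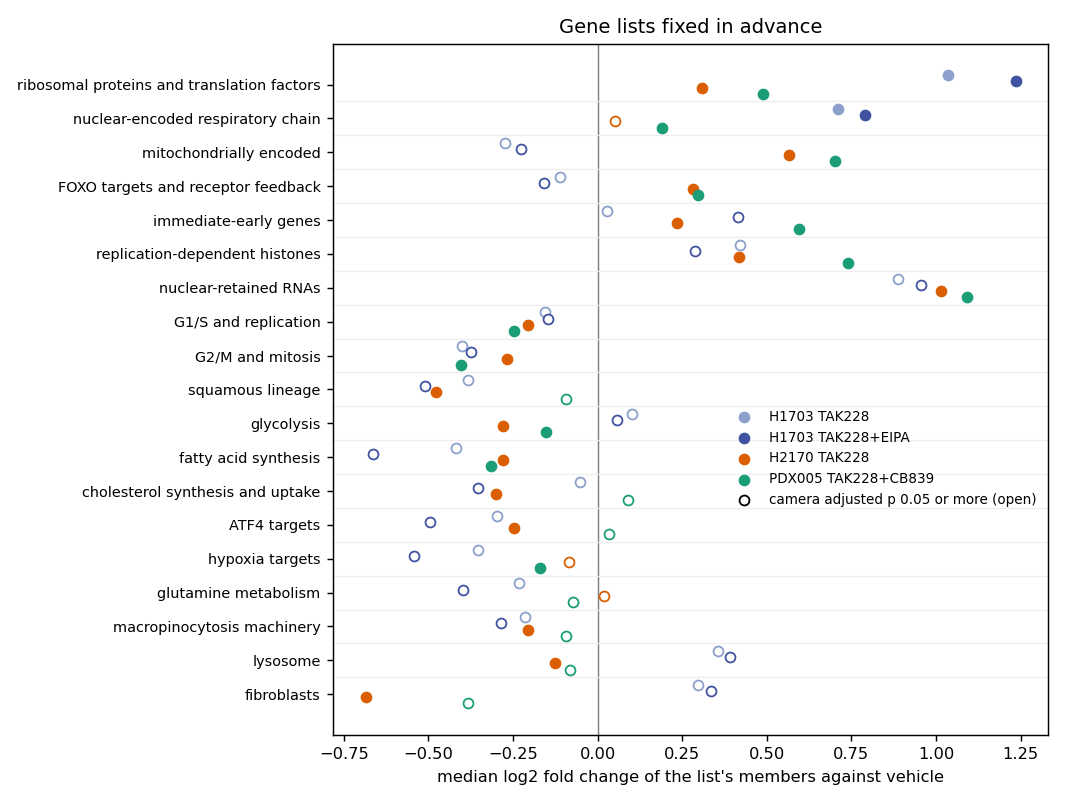
Median log2 fold change against vehicle (x axis) of the members of 19 gene lists fixed in advance (y axis), with points coloured by comparison and filled where camera's adjusted p with the preset correlation was under 0.05. The ribosomal list lay above 0 in the 4 comparisons, at 1.04, 1.24, 0.31 and 0.49, and no filled point stayed under 0.05 with an estimated correlation.

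PDX005 tumours given TAK228+CB839 were compared with vehicle to follow combined inhibition of mTOR and of glutamine use. IRS2 rose by 1.76 ± 0.09, from 31.1 ± 3.71 to 105 ± 6.98 CPM (SD, n = 5), and EGR1 by 1.85 ± 0.09. TXNIP rose by 1.72 ± 0.22, and PDK4, which restrains pyruvate oxidation, by 1.87 ± 0.28. DDIT4 fell by 1.59 ± 0.13, from 173 ± 26.3 to 57.7 ± 10.2 CPM, MKI67 by 0.97 ± 0.09, and the cytokine gene IL6 (hg38 chromosome 7, 22725884 to 22732002) by 1.77 ± 0.24. In limma 4421 of 15294 genes passed, 2150 higher and 2271 lower, of which 563 changed more than 2-fold. The treated and vehicle libraries did not overlap in 20.6% of genes, against 0.794% by chance. The other leading rises were C2CD4A (2.13 ± 0.22), the activin subunit gene INHBA (2.06 ± 0.38), the esterase gene AADAC (2.05 ± 0.25) and the heat shock gene HSPA6 (2.02 ± 0.32). The other leading falls were CD177 (-2.04 ± 0.24), POMK (-1.94 ± 0.28), the lanosterol synthase LSS (-1.90 ± 0.22), the serotonin receptor HTR2B (-1.83 ± 0.36) and NOMO2 (-1.99 ± 0.33), which is uncertain because it has near-identical copies.

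Camera called 13 of 38 lists in PDX005, with cell cycle lists lower and FOXO targets higher. Of 30 G2/M genes 19 fell and 0 rose (21 lower over the list alone, camera adjusted p = 9.05e-07, and adjusted p = 0.878 with an estimated correlation), including BUB1 (-0.71 ± 0.09) and DLGAP5 (-0.80 ± 0.11). Of 32 G1/S genes 16 fell and 3 rose (17 and 3 over the list alone, camera adjusted p = 0.00184, and adjusted p = 0.93 with an estimated correlation), including CDC25A (-1.31 ± 0.12) and GINS1 (-0.50 ± 0.11). Of 22 FOXO target genes 12 rose and 1 fell, the same counts as over the list alone (camera adjusted p = 0.000385, and adjusted p = 0.716 with an estimated correlation), including BCL6 (1.22 ± 0.11) and GADD45A (1.18 ± 0.13). Of 82 ribosomal protein and translation factor genes 65 rose and 1 fell (68 and 1 over the list alone), with a median of 0.49, or 0.31 after the length and GC correction (camera adjusted p = 4.3e-20, and adjusted p = 0.878 with an estimated correlation). RPL37 rose by 0.81 ± 0.11, RPS21 by 0.77 ± 0.10, RPL38 by 0.76 ± 0.10 and RPL14 by 0.67 ± 0.08. Of 14 immediate-early genes 8 rose and 1 fell, also over the list alone, with KLF2 at 1.62 ± 0.18 and FOSB at 1.33 ± 0.17 (camera adjusted p = 4.52e-05, and adjusted p = 0.275 with an estimated correlation). The respiratory chain list held 10 rises, such as COX6A1 (0.50 ± 0.10), and 3 falls, such as NDUFS1 (-0.54 ± 0.08), among 43 members (camera adjusted p = 0.0463, and adjusted p = 0.976 with an estimated correlation). COX6A1 did not pass after the length and GC correction (adjusted p = 0.0810), and the list turned down there (0.875). The list's call was also lost without vehicle replicates 1 or 4 (0.113 and 0.247) or TAK228+CB839 replicates 2, 3 or 4 (0.155, 0.0757 and 0.0599) and with a pseudocount of 5 (0.0522).

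Metabolic lists were lower in PDX005, while the glutamine list was not called. The glutamine synthetase GLUL stood at -0.29 ± 0.11 (adjusted p = 0.0635). Its adjusted p under alternatives ran from 0.00734 (-0.37, with quantile normalisation) to 0.307. Of 21 glutamine metabolism genes 1 rose and 6 fell, also over the list alone (camera adjusted p = 0.432). The rise was ASNS, the asparagine synthetase, at 0.60 ± 0.13, and the falls included the pyrimidine synthesis genes CAD (-0.52 ± 0.09) and CTPS1 (-0.40 ± 0.08) and the glutathione synthesis gene GCLC (-0.46 ± 0.09). Of 12 fatty acid synthesis genes 6 fell and 1 rose (7 lower over the list alone, camera adjusted p = 0.00712, and adjusted p = 0.93 with an estimated correlation), with FADS2 at -0.86 ± 0.11 and the lipogenic regulator SREBF1 at -0.59 ± 0.13. Of 21 glycolysis genes 6 fell, also over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.93 with an estimated correlation): PFKFB3 by 1.01 ± 0.14, PGAM1 by 0.62 ± 0.10 and the glucose transporter SLC2A1 by 0.45 ± 0.10 among them. Of 24 hypoxia targets 6 fell, also over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.93 with an estimated correlation), including EGLN3 (-1.33 ± 0.18), ADM (-0.74 ± 0.10) and LOX (-1.03 ± 0.16), while VEGFA stood at -0.19 ± 0.22 (adjusted p = 0.538). The hypoxia call was lost without vehicle replicate 4 or TAK228+CB839 replicate 4 (0.138 and 0.0603), with quantile normalisation (0.0641) and after the length and GC correction (0.0915). Of 32 ATF4 targets 2 rose and 10 fell, with VLDLR at -1.04 ± 0.14 and CHAC1 at -1.45 ± 0.26, and the list's median (0.03) and mean (-0.08) differed in sign (camera adjusted p = 0.656). HMGCS1 stood at -0.00 ± 0.18, SLC7A5 at -0.09 ± 0.15 and SDC1 at -0.23 ± 0.14, none of which passed.

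TP63 fell by 0.47 ± 0.12 in PDX005 (-0.35, adjusted p = 0.0547, after the length and GC correction), and the squamous genes FAT2 (-1.07 ± 0.10) and BNC1 (-1.40 ± 0.15) fell while KRT17 rose by 0.69 ± 0.15. The squamous list was not called (1 rise and 5 falls among 24, camera adjusted p = 0.437), and SOX2 stood at -0.05 ± 0.11. Lists of RNA classes were called higher in the same tumours. Of 6 genes on the list named nuclear-retained RNAs 5 rose, also over the list alone (camera adjusted p = 0.00383, and adjusted p = 0.878 with an estimated correlation). They included NEAT1 (1.49 ± 0.24), MALAT1 (1.09 ± 0.26) and the small nucleolar RNA host genes GAS5 (1.12 ± 0.14) and SNHG1 (1.10 ± 0.14). With such host genes among its members the list does not measure nuclear retention alone. TAK228+CB839 replicate 1 stood apart as the highest of its group in the mean of this list (8.99 log2 CPM against 8.31 in the next library), NEAT1 (11.19 against 10.11) and SNHG1 (6.37 against 5.82). Of 13 mitochondrially encoded genes 8 rose (13 over the list alone, camera adjusted p = 0.000258, and adjusted p = 0.93 with an estimated correlation), including ND3 (0.93 ± 0.18) and ND1 (0.85 ± 0.23), in which the same library stood apart as the highest (13.38 against 13.05). Of 15 histone genes 9 rose (12 over the list alone, camera adjusted p = 6.38e-06, and adjusted p = 0.275 with an estimated correlation), including H2BC5 (0.93 ± 0.11) and H1-2 (0.99 ± 0.12). The endothelial gene VWF fell by 1.33 ± 0.28 and the collagen gene COL1A2 by 1.28 ± 0.28, while the endothelial and fibroblast lists were not called (camera adjusted p = 0.515 and 0.229). That library was also the lowest of its group in the endothelial mean (-0.68 against 0.15).

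**Figure D4:**
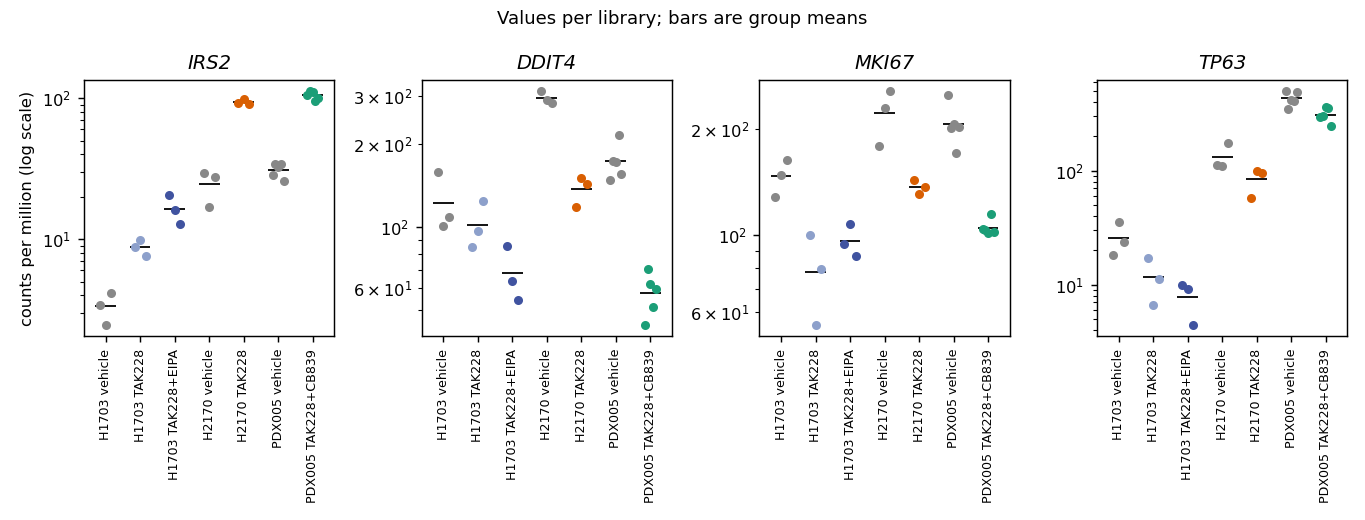
CPM (y axis, log scale) of IRS2, DDIT4, MKI67 and TP63 in each library, with 1 point per library, groups on the x axis and bars at the group means. The IRS2 values of every drug-treated group lay above those of the vehicle group of the same model.

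Whether H2170 and H1703 responded differently to TAK228 was tested as the difference between their log2 fold changes (H2170 minus H1703). EGR1 responded more in H2170, by 2.19 ± 0.44, with 2.85 there and 0.66 in H1703. DUSP4, a phosphatase of ERK-type kinases, stood at -1.05 in H2170 and 1.90 in H1703, a difference of -2.96 ± 0.50, and COL6A2 at -0.94 and 0.91, a difference of -1.84 ± 0.28. The arginine sensor of mTOR complex 1 CASTOR1 differed by -1.84 ± 0.36, the splicing factor PUF60 by -2.13 ± 0.35 and PDZD2 by -1.82 ± 0.44. SNED1 (2.74 ± 0.61), the pseudogene KLRA1P (2.40 ± 0.59), ZNF493 (2.37 ± 0.47) and the RNA-binding protein RBM24 (2.34 ± 0.50) had the other leading positive differences. In limma 405 of 11817 genes differed, 226 with the higher and 179 with the lower response in H2170. The ribosomal list (camera adjusted p = 2.53e-11, and adjusted p = 0.761 with an estimated correlation) and the respiratory chain list (camera adjusted p = 3.49e-09, and adjusted p = 0.761 with an estimated correlation) responded less in H2170, with median differences of -0.81 and -0.72 (-0.51 and -0.45 after the length and GC correction), and 0 and 1 members that differed on their own (0 and 16 lower over the list alone, with 1 respiratory gene higher). The lysosome list, which was called lower in H2170 itself, had lower fold changes there than in H1703 (camera adjusted p = 0.00149, and adjusted p = 0.761 with an estimated correlation). The mitochondrially encoded list had higher ones (camera adjusted p = 0.00201, and adjusted p = 0.761 with an estimated correlation), a call lost without H1703 TAK228 replicate 1 (0.0705). Camera called 8 of 34 lists, and 4 without H1703 TAK228 replicate 1 or H2170 TAK228 replicate 1. The count of differing genes was 6595 with array weights and 228 with no filter. Leaving out libraries moved it too: it was 4868 without H1703 TAK228 replicate 1, 57 without H1703 vehicle replicate 2, 2 without H1703 TAK228 replicate 2 or H2170 vehicle unnumbered-b, and 0 without H1703 vehicle replicate 3, H1703 TAK228 replicate 3 or any other H2170 library. Each of the 10 genes named here lost its call without H1703 vehicle replicate 3, H1703 TAK228 replicate 2, H1703 TAK228 replicate 3 or any 1 H2170 library, with adjusted p between 0.0512 and 0.137, SNED1 also without H1703 vehicle replicate 1 (0.0510), and 6 of them also without H1703 vehicle replicate 2 (0.0530 to 0.0676). The differences also followed transcript length and GC content, which went with 36.1% of their variance across genes. KLRA1P and CASTOR1 did not pass after the length and GC correction (adjusted p = 0.0651 and 0.0767).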

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

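Of the tests in this part, the length and GC correction of the TAK228+EIPA calls (both of its tests) and the matched lists for ribosomal genes were chosen after the results were seen.

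In H1703 tumours under TAK228+EIPA, 5841 genes passed against vehicle, and their fold changes followed transcript length (43.0% of the variance of all fold changes went with length and GC content). A trend of the additive form that the correction subtracts is argued against as the whole cause. After the correction 3344 of 12757 genes passed, and 908 to 3926 did without any 1 of the 6 libraries, each over 5% of the genes tested. Of the 3344 genes, 2329 had also passed in the same direction before it. A library effect of another form in length or GC content would outlast the subtraction, so such an effect stays open. How much of the change the trend explains stays open, because 40.2% of the genes that passed stayed past the threshold in the same direction. Vehicle replicate 3 also leaned to long transcripts against the other libraries. Its deviation from the vehicle mean had a rho with length of 0.55 across genes. The deviations of the other vehicle libraries had -0.35 and -0.28, and those of the treated ones -0.48, -0.51 and -0.47. As replicate 3 enters that mean, these values are not independent of each other. A response to TAK228 that the models share may account for part of it: 76.4% of the genes called in the same direction in H2170 and PDX005 (763 of 999) had that direction here after the correction, where over 75% had been set beforehand as what it needs. Of these genes 335 passed in that direction after the correction and 31 in the opposite one.

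TAK228 replicate 1 of H1703 lay nearer to the vehicle libraries than replicates 2 and 3, and without it 6395 genes passed in place of 0. On a score of the genes that H2170 and PDX005 share it lay at 0.406 of the way from the vehicle mean to the mean of the other TAK228 libraries before correction for length and GC content and at 0.441 after it, where the other 2 lay at 1.40 and 0.60. The correction took the rho with length of its deviation from the vehicle mean from -0.45 to -0.03. Its place on the score moved little, but 0.441 lies under the bound of 0.5 set beforehand by less than the SD of 0.229 over the 3 vehicle libraries. A vehicle library under its label would lie within the vehicle range, and it lay above the highest vehicle library by 0.552 of that range, while an exchange with a vehicle library would put 1 of these high, and the highest lay at 0.194. With that spread the length trend, a wrong label and an exchange cannot be told apart, and a weaker response of that tumour was not tested.

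Ribosomal protein and translation factor genes were higher as a list in the 4 comparisons with vehicle, with medians of 1.04, 1.24, 0.31 and 0.49. Part of it went with their short length, GC content and expression: 10000 matched random lists had medians of 0.51, 0.59, 0.03 and 0.15. The list's median lay at the percentile 100 of these in each comparison, so these properties, as matched, do not account for all of it. How close the matched genes came was not measured, and length was that of the longest annotated transcript. A larger part for length, GC content and expression therefore stays open. The random lists drew genes independently, so for members that move together the percentile overstates the certainty. Reads moving from processed pseudogenes to their parent genes would lower the pseudogenes, and the lowest of their 4 medians was 0.29. That test cannot decide the question, since pseudogenes share sequence with their parents and their counts can follow them. A slower loss of these mRNAs, which share a 5' motif through which mTOR governs translation, remains a biological hypothesis that was not tested, and RNA quality and the preset correlation stay open.

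Whether other splits of the same libraries give results as large was counted for every comparison, with the count of splits at or above the real one including the real split. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real and the highest other count of genes were 0 and 0 for H1703 TAK228 (10 splits as large), 5841 and 0 for TAK228+EIPA (1 split), 2005 and 0 for H2170 (1 split), and 1 and 914 for TAK228+EIPA against TAK228 (2 splits). The split with 914 set TAK228 replicate 2 with TAK228+EIPA replicates 1 and 3 against the rest, which points to a structure of these libraries other than the treatment. In PDX005 chance was excluded for genes, with 4421 against 9 in the highest of 99 other splits (1 of 100). For the difference between models 3 of 100 splits gave 405 genes or more, and the highest gave 2708. That split kept the H1703 groups and mixed the H2170 ones, so it carries the H1703 response, and such splits do not test the difference itself. Counts of lists fared differently: the real and highest other counts were 2 and 22 for H1703 TAK228 (10 of 10), 2 and 16 for TAK228+EIPA (10 of 10), 20 and 18 for H2170 (1 of 10), and 3 and 12 for TAK228+EIPA against TAK228 (10 of 10). Chance was not excluded for the list count of PDX005 (13, highest other 23, 44 of 100 splits as large). The counts for the difference between models were 8 and 22 (71 of 100), with the same limit as for its genes.

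The groups of 5 PDX005 libraries were searched for a library far from the other 4 by Dixon's test, the gap to its neighbour divided by the range, in 228 values, of which 24 passed against 11.4 by chance. TAK228+CB839 replicate 1 held 10 of the 24. It was the highest of its group in PFKFB3 (0.791), NEAT1 (0.774), SNHG1 (0.801), ND1 (0.807), EPHA2 (0.804) and the mean of nuclear-retained RNAs (0.724), and the lowest in CCND1 (0.844) and the means of tRNA synthetases (0.792), TCA cycle (0.865) and endothelial genes (0.711). TAK228+CB839 replicate 2 was the lowest in CD177 (0.790) and the highest in RPS21 (0.756), and replicate 3 the highest in C2CD4A (0.757) and FADS2 (0.861). TAK228+CB839 replicate 4 was the highest in MKI67 (0.775) and amino acid transporters (0.804) and the lowest in KLF2 (0.815), and replicate 5 the lowest in GINS1 (0.736). Vehicle replicate 5 was the highest in TXNIP (0.761) and SDC1 (0.794) and the lowest in INHBA (0.773) and angiogenic factors (0.725). Vehicle replicate 3 was the lowest in NEAT1 (0.729) and vehicle replicate 4 the highest in SLC2A1 (0.744).

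The TAK228 response differed between H2170 and H1703, by the interaction term in limma, in 405 genes. These differences followed transcript length and GC content across genes (rho 0.46 and -0.54), which went with 36.1% of their variance. After the length and GC correction 366 genes differed, and 55.6% of the calls that could be corrected (223 genes) stayed in the same direction. Camera called 8 lists for that term, of which 0 stayed with an estimated correlation (smallest adjusted p 0.761) and 0 were called by fry. Among named genes the response in H2170 was higher by 2.74 in SNED1, 2.40 in KLRA1P, 2.37 in ZNF493, 2.34 in RBM24, 2.19 in EGR1, 1.86 in KLHL24, 1.44 in LRRC8B, 1.42 in RAB5A, 1.33 in ZNF107 and 1.26 in PHLPP2 (log2). The differences below 0 were -2.96 in DUSP4, -2.13 in PUF60, -1.84 in COL6A2, -1.84 in CASTOR1, -1.82 in PDZD2, -1.36 in TMEM54, -1.27 in SDC1, -1.18 in FADS2 and -1.01 in EHD1. The adjusted p of these genes lay between 0.0254 and 0.0479. The count was 4868 without H1703 TAK228 replicate 1, 57 without H1703 vehicle replicate 2 and 0 to 2 without any other library but H1703 vehicle replicate 1, where it was 501.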

How the results depend on the processing

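The length and GC correction, the voom weights and the replicate block in H2170 under each order of its unnumbered libraries were chosen after the data were seen, and the other alternatives before. Planned tests with count models were not run because the deposited values are log2 values, although whole reads could be recovered from them. In H2170 2 vehicle columns share a header, so the block was fitted with unnumbered-a as replicate 1 and as replicate 2. The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.23, 0.25 and -0.46 for H1703 TAK228, -0.34, -0.17 and -0.22 for TAK228+EIPA, -0.06 to 0.07 for PDX005, 0.12, -0.13 and 0.18 for H2170 with unnumbered-a as replicate 1, 0.13, -0.01 and 0.18 with it as replicate 2, and -0.15, -0.64 and 0.42 between the H1703 TAK228 and TAK228+EIPA libraries. Of these, replicate 2 of H1703 TAK228 with vehicle, replicates 1 and 3 of H2170 in either order and replicate 3 of the last set correlated best with their own number. With the replicate block 1303 genes passed for H1703 TAK228, 4959 for TAK228+EIPA, 4272 for PDX005, 2668 and 2676 for H2170 in the 2 orders and 0 in both for the difference between models (3334 and 3342 at an unadjusted p under 0.05), and the lists called for H1703 TAK228 were 5 in place of 2. Under TAK228+EIPA the block ended the calls of SLC7A5, MKI67 and SDC1 (adjusted p = 0.0531, 0.0553 and 0.0610), and in PDX005 that of EPHA2 (0.0686). In H2170 it ended the call of 0 named genes, and TP63 passed (0.0273 and 0.0116). For the difference between models it ended every call, the 10 genes named in the report standing at 0.120 and 0.116.

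With each library left out in turn the genes passing ran from 0 to 6395 for H1703 TAK228 (6395 without TAK228 replicate 1), 2843 to 6589 for TAK228+EIPA, 735 to 1648 for H2170, 3416 to 4369 for PDX005, 0 to 1 for TAK228+EIPA against TAK228 and 0 to 4868 for the difference between models. The lists called ran from 2 to 8, 2 to 5, 16 to 22, 10 to 14, 2 to 8 and 4 to 11 in the same order. Array weights gave 8830 genes for TAK228+EIPA and 6595 for the difference between models, where no filter gave 228. The length and GC correction gave 3344 genes for TAK228+EIPA and 5 lists for H1703 TAK228, and quantile normalisation 4 lists there. With only the 6 drug-treated libraries 0 genes passed for TAK228+EIPA against TAK228. An estimated correlation left 0 lists in each of the 6 comparisons, and fry gave 0 for H1703 TAK228, 3 for TAK228+EIPA, 3 for H2170, 6 for PDX005, 0 for TAK228+EIPA against TAK228 and 0 for the difference between models. The 3 for TAK228+EIPA were all lower and held neither list reported there, the ribosomal and respiratory chain lists standing at adjusted p of 0.101 and 0.0546. Fewer libraries leave fewer degrees of freedom, and for the other moves the cause was not tested. The other counts of genes and lists stayed within 1.5 times the reported ones, which does not say that the genes and lists were the same.

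The 226 genes and comparisons named gave 2686 values under alternatives, of which 2454 kept direction and side of the threshold, 166 lost the call, 46 gained it and 20 changed direction, none of them in a gene that had passed. The changes of direction were in values near 0 and the cause was not tested. In H2170 VEGFA went to 0.0410 with quantile normalisation, 0.0498 with the length and GC correction and ran from -0.15 to 0.15 with libraries left out. ASNS went to -0.0138 with the correction and ran from -0.0406 to 0.12, SOX2 ran from -0.0659 to 0.23 and HMGCS1 from -0.29 to 0.00799. In PDX005 HMGCS1 went to 0.0295 with quantile normalisation and 0.0208 with the correction and ran from -0.12 to 0.16 with libraries left out, SOX2 from -0.14 to 0.0143 and SLC7A5 from -0.19 to 0.00335. Depth limits which genes were tested: 14845 of 27777 listed genes had enough reads in H2170 and 15294 of 27778 in PDX005, and the H1703 tables had lost their low genes before deposit. The recovery of 2-fold changes in simulated data (22%, 51.5% and 72% for H1703 TAK228, H2170 and PDX005) also goes with group size and spread, which were not separated from depth.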

Other observations

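The ERK pathway test in this part was chosen after the result was seen, and so were the genes named here outside the rule.

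H2170 under TAK228 and PDX005 under TAK228+CB839 shared many genes, with no library in common. Of 13827 genes tested in both, 506 rose in both, against 130 for independent lists of that size, and 633 fell in both, against 166. In all, 1 that rose and 6 that fell in H2170 went the opposite way in PDX005. Across genes the fold changes correlated at r = 0.589 and rho = 0.621, and genes are not independent replicates. PIK3R1 fell by 1.24 ± 0.18 in H2170 and by 1.54 ± 0.13 in PDX005, and PIK3R3, which encodes another regulatory subunit of PI 3-kinase, by 1.51 ± 0.13 and 1.75 ± 0.15. RHEBL1, a relative of the mTOR activator RHEB, rose by 1.77 ± 0.27 and 2.16 ± 0.27. The transferrin receptor gene TFRC fell by 1.27 ± 0.17 and 0.98 ± 0.13, and POMK, which modifies dystroglycan, by 1.84 ± 0.36 and 1.94 ± 0.28. These genes were chosen after their values were seen, from the 60 shared genes with the largest mean change over H2170, PDX005 and H1703 under TAK228+EIPA.

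As H1703 entered that ranking, its values for these genes are given without being a separate test. Under TAK228+EIPA PIK3R1 fell by 1.64 ± 0.31, PIK3R3 by 1.28 ± 0.22, TFRC by 1.77 ± 0.27 and POMK by 2.28 ± 0.48, and RHEBL1 rose by 1.64 ± 0.27. After the length and GC correction these stood at -0.90, -0.77, -1.13, -2.58 and 0.92, and HIF1A and OAS3 at -2.11 and -2.45, all with adjusted p of 0.0270 or less. HIF1A fell by 2.78 ± 0.31 there and by 0.87 ± 0.13 in PDX005. In H2170 it stood at -0.61 ± 0.17 with all libraries, and its adjusted p was 0.0810, 0.0874 and 0.133 without vehicle unnumbered-a, vehicle unnumbered-b and vehicle replicate 3, and 0.0651 with quantile normalisation. OAS3 fell by 2.63 ± 0.32 in H1703 and by 1.21 ± 0.22 in PDX005, and stood at -1.15 ± 0.30 in H2170, with adjusted p of 0.0521, 0.0841 and 0.114 without the same vehicle libraries.

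EGR1 and DUSP6, both known as outputs of the ERK pathway, rose in H2170 (2.85 and 1.59 ± 0.17) and in PDX005 (1.85 and 1.77 ± 0.15), and a candidate explanation is a higher output of that pathway as feedback after mTOR inhibition. A list of 13 other genes known as its outputs argues against this for both models together, since 30.8% of them had fold changes above 0 in both models, where over 75% was set as what the explanation needs. That bound asks for values above 0 in both models at once, which is stricter than the same share in each model. In H2170 0 of the 13 rose and 4 fell, and 5 had fold changes above 0. DUSP4 fell by 1.05 ± 0.12, EPHA2 by 0.80 ± 0.12 and CCND1 by 0.70 ± 0.10. ETV5 fell by 0.39 ± 0.11 with all libraries, with an adjusted p of 0.101, 0.104, 0.137, 0.118 and 0.0541 without vehicle unnumbered-a, vehicle unnumbered-b, vehicle replicate 3, TAK228 replicate 2 and TAK228 replicate 3. It was 0.0603 with quantile normalisation and 0.0565 after the length and GC correction. In PDX005 3 of the 13 rose and 1 fell, and 7 had fold changes above 0. For that model alone the explanation stays open. SPRY2 rose there by 0.66 ± 0.12 and DUSP5 by 0.61 ± 0.13. EPHA2 rose by 0.37 ± 0.12, with adjusted p of 0.0518 to 0.0695 without vehicle replicates 1, 2 or 3 or TAK228+CB839 replicates 1, 2, 3 or 4. CCND1 fell by 0.41 ± 0.10 (adjusted p = 0.0529 after the length and GC correction).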
